A study of Homo sapiens with 30 samples.

How the data were processed

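CAL-1 cells, an established human line with features of plasmacytoid dendritic cells, were profiled by mRNA sequencing in 30 libraries that formed 10 groups of 3. Per the labels' protocols, cells received R848 at 1 µg/ml or were nucleofected with 1 µg of RNA on an Amaxa 96-well shuttle, mRNA was isolated with the miRNeasy kit, and stranded TruSeq libraries were sequenced as paired ends on a NextSeq 500. Those protocols give 2 h for R848, while each library's own label gives 6 h or 16 h. The libraries were grouped by their own labels.

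The deposited table holds whole-number counts per gene symbol for 25066 genes, which the authors made from the reads. Per the submitters' processing notes, FastQC 0.11.3, cutadapt 1.8.3, STAR 2.4.2 and limma 3.26.9 were used, with no role or order given. The counting program, its strand setting, the genome build and the annotation were not given in the sources used here, so no coordinates are printed and genes keep the table's symbols. Of those symbols, 20431 (81.5%) were current or older symbols of the gene name table. The table has 32 value columns. In 2 of them, R848 16 h replicate 3 and pU/UC 16 h replicate 3, a library appears again with every value equal, and each was used once, leaving 30 columns. Column names end in sample numbers S1 to S15, each shared by 2 libraries. What these numbers mark is not stated, and they entered no model. No symbol started with MT-, so the list of mitochondrially encoded genes had 0 measured members.

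Total counts per library ranged from 27 M to 53.4 M (median 36.9 M). In a single library, 3 counts corresponded to 0.0567 to 0.116 CPM. For a gene at 0 in every library of a group, the fold is given as a lower bound against 3 counts over that group. Floors cover counting error only, since reads amplified without molecular identifiers are not independent molecules.

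The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 10 groups (13973 genes), libraries were scaled by TMM, and all 30 libraries entered a single model with a mean per group and 20 residual degrees of freedom. Contrasts were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, two-sided, at an adjusted p under 0.05. Every adjusted p of a single gene below comes from that test unless another tool is named. CPM values are TMM-scaled group means ± SD over 3 libraries, and log2 fold changes carry their SE. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

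Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 measured lists of a comparison. Camera with an estimated correlation and fry were run beside it. The lists were interferon genes, interferon-stimulated genes, inflammatory cytokines, chemokines, NF-kB family and targets, dendritic cell maturation, MHC class I and class II presentation, plasmacytoid dendritic cell identity, the IRF family, nucleic acid sensing and signalling, and interferon receptors with JAK-STAT regulators. Further lists were immediate early and AP-1 genes, S phase, G2 and mitosis, MYC and ribosome biogenesis, cholesterol synthesis, glycolysis and hypoxia, unfolded protein and integrated stress response, p53 targets and cell death, heat shock and oxidative stress, cytosolic ribosomal proteins, and replication-dependent histones. Markers of conventional dendritic cells, monocytes and macrophages, T and NK cells, B and plasma cells, and stromal and epithelial cells completed the set. Counts of list members are given over all genes tested and, in those words, adjusted over the list alone.

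The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. For R848 versus vehicle, pU/UC versus no RNA and pU/UC versus xRNA, the rule took the 6 largest rises and 6 largest falls among genes past the test with a mean of at least 1 CPM in the higher group and no overlap between the groups' libraries. It added the 2 members of each list with the smallest adjusted p, markers of other cell types excepted. IRF3, IRF5, IRF7, IFNB1, IL29 (IFNL1), TNF, IL6, IL12B, CXCL10, ISG15, IFIT1, DDX58 (RIG-I) and TLR7 were always included. For xRNA versus no RNA, no RNA versus vehicle and the interactions, 4 genes each way and the always-included genes were taken. Other genes named as the members behind a small count, and HMGCS1 and LYZ in the comparison of no RNA between times, were chosen after their values were seen. Text names a subset of these genes.

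Alternatives were DESeq2 1.42.0 size factors, no low-count filter, a stricter filter, the DESeq2 test, limma voom, a fit with only the compared groups, the replicate number as a block, and leaving out each library in turn. Offsets that remove each library's trend along transcript GC content, and contrasts between the R848 and xRNA effects, between times within a group and of the xRNA effect between times, were added after seeing the data. GC values were found for 12476 tested genes (89.3%). The tests of edgeR, limma voom and DESeq2, and camera with the preset correlation, were run on simulated counts with 200 changed genes. For pU/UC versus no RNA at 6 h (13876 genes), edgeR recovered 31, 39, 50 and 50 of 50 genes changed 1.5-, 2-, 4- and 8-fold, with 3 unchanged genes among 173 calls. For xRNA versus no RNA at 6 h (13816 genes), it recovered 32, 42, 50 and 50 of 50, with 11 unchanged genes among 185 calls. In the same simulations limma voom called 3 unchanged genes among 173 and 8 among 181, and DESeq2 22 among 197 and 25 among 203. Camera called 0 of 27 unchanged lists in either simulation. Genes were simulated independently and without a GC trend, with the dispersions that edgeR had estimated for the genes its filter kept. These runs therefore do not show how camera or the gene tests behave with correlated genes, and they do not rank the tools.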

Results

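Gene expression was measured by mRNA sequencing in CAL-1, a human cell line used as a model of plasmacytoid dendritic cells, which sense viral nucleic acids and release type I interferon. The 30 libraries formed 10 groups of 3: R848, vehicle, pU/UC RNA, xRNA and no RNA, each at 6 h and 16 h. R848 is a small-molecule agonist of the endosomal receptors TLR7 and TLR8. The pU/UC RNA carries a motif of the hepatitis C virus genome known as a ligand of RIG-I, and xRNA is named as its control in the series' design. The RNA was delivered by nucleofection, and the no RNA libraries are the stated baseline for that arm. Libraries held 27 M to 53.4 M counts (median 36.9 M), and 13973 of 25066 genes were tested. Levels below are CPM, counts scaled to a common library total, as mean ± SD with n = 3, and log2 fold changes are given ± SE.

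Each library's mean correlation across genes with the other libraries of its group was 0.985 to 0.993 on the log2 scale, where genes are not independent replicates. Pairs within a group differed by more than sampling noise, with chi-square per degree of freedom of 3.71 to 120 over 30 pairs. The first 3 principal components held 32.2%, 18.3% and 13.9% of the variance. Libraries of a group also differed along the GC content of their genes, with slopes of deviations from the group mean between -0.28 and 0.29 log2 units per 10 points of GC. The 10 most abundant genes took 3.07% to 4.57% of counts.

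Interferon genes were high in the libraries labelled xRNA and not in those labelled pU/UC, opposite to the roles the design text gives these RNAs. IFNB1, the gene of interferon beta, stood at 155 ± 7.12 CPM in the libraries labelled xRNA at 6 h, against 0.384 ± 0.297 CPM in those labelled pU/UC and 1.28 ± 0.272 CPM without RNA. The majority direction among called genes turned under at least 1 of 8 alternatives in 13 of 16 comparisons and contrasts, and in none of the 3 that set pU/UC against no RNA. All directions below follow the labels as deposited, and the groups are named by those labels throughout.

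**Figure D1:**
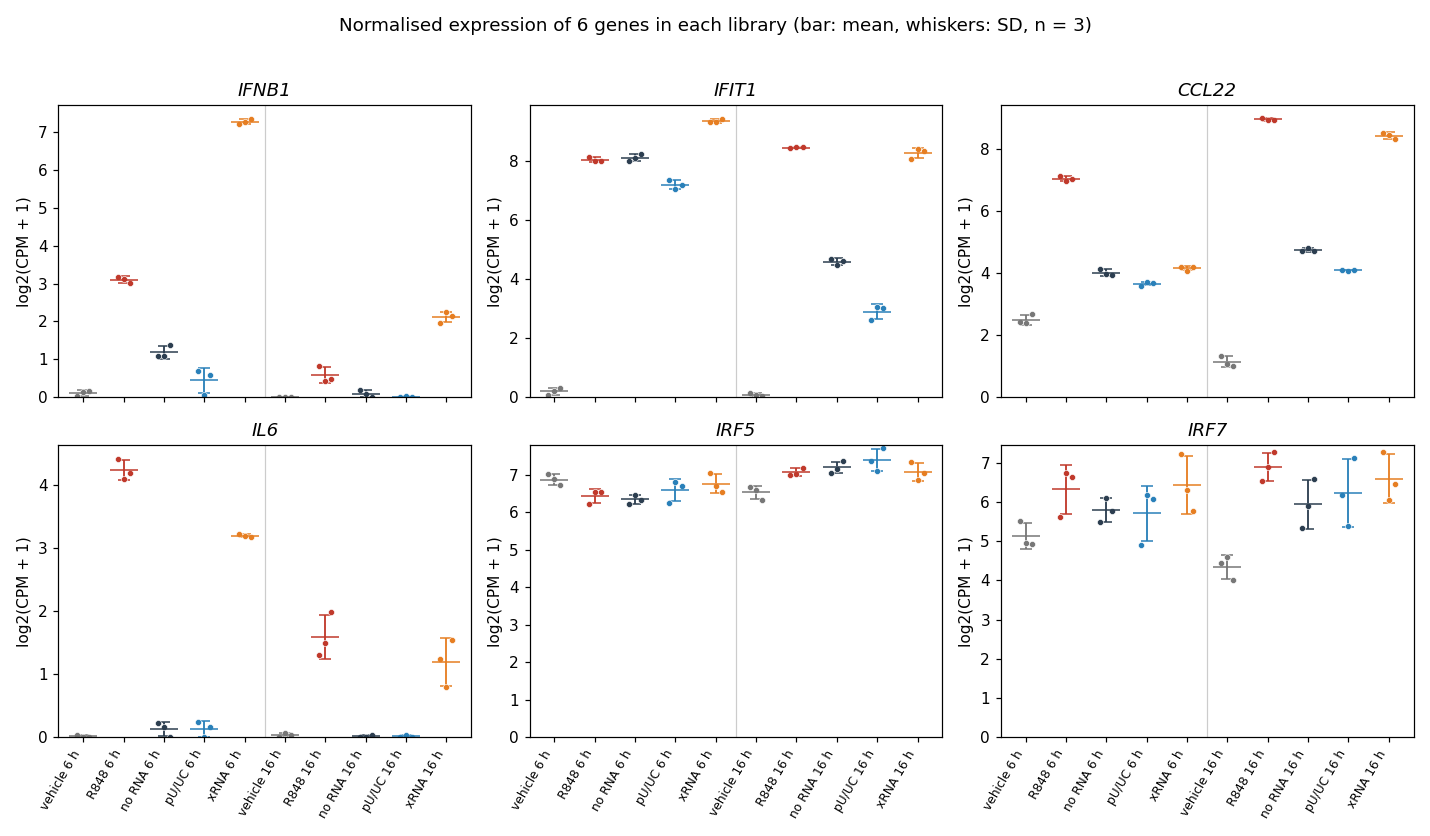
Levels of IFNB1, IFIT1, CCL22, IL6, IRF5 and IRF7 in each of the 30 libraries by group, as log2(CPM + 1), with bars at the mean and whiskers at the SD of 3 libraries. IFNB1 reached 155 ± 7.12 CPM in xRNA at 6 h and 7.63 ± 0.489 CPM in R848 at 6 h, and IFIT1 lay at 0.145 ± 0.0997 CPM or below in the vehicle groups.

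R848 versus vehicle asked how TLR7/8 stimulation changed these cells. At 6 h, 74 of 78 measured interferon-stimulated genes rose (74 adjusted over the list alone), with a median log2 fold change of 3.72 (camera, adjusted p = 1.02e-44). MX1, an antiviral GTPase, rose from 7.26 ± 1.64 to 1620 ± 18.4 CPM, and OAS2, a sensor of double-stranded RNA upstream of RNase L, rose from 5.27 ± 0.743 to 1620 ± 140 CPM. IFIT1, which binds viral RNA, rose from 0.145 ± 0.0997 to 265 ± 14.6 CPM. IFI44, another interferon-induced gene, had no count in vehicle and was at least 1490-fold higher at 32.5 ± 3.4 CPM. Among the 18 measured interferon genes, IFNB1, IL29 and IL28B rose (3 adjusted over the list alone, 5 over all genes with GC offsets), and the list was not called (camera, adjusted p = 0.22). Its median log2 fold change was 2.01, and 0.45 with the 16 genes that had a group without counts set at their bounds. IFNB1 rose 91.3-fold to 7.63 ± 0.489 CPM. IL29, a type III interferon, was at 0.86 ± 0.409 CPM against 0.00688 ± 0.0119 CPM. Among MX1, OAS2, IFIT1, IFI44, IFNB1 and IL29, the largest adjusted p was 5.20e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

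Inflammatory genes rose with them. Of 22 inflammatory cytokines 17 rose, of 16 chemokines 14 rose and of 36 NF-kB family members and targets 29 rose (17, 14 and 30 adjusted over the list alone), with camera adjusted p of 4.83e-07, 8.85e-10 and 9.27e-13. The exceptions that fell were LIF and TGFB1, CXCL16, and SOD2 and PLAU. IL23A, a subunit of IL-23, rose 24.3-fold to 66.5 ± 8.63 CPM, and the lymphotoxin gene LTA rose 8.01-fold to 369 ± 11 CPM. IL6 was at 17.9 ± 2.17 CPM against 0.00688 ± 0.0119 CPM, IL12B, the p40 subunit of IL-12, at 1.31 ± 0.484 CPM against no count (at least 60.1-fold higher), and TNF rose 1.36-fold to 288 ± 9.07 CPM. CCL22, a ligand of CCR4, rose 27.9-fold to 131 ± 7.7 CPM. CCL3 and CCL4 had no count in vehicle and were at least 545-fold and 1050-fold higher, and their near-identical copies make the assignment of reads between them uncertain. The chemokine median was 7.78, and 5.45 with 8 genes at their bounds. BCL2A1, an NF-kB-driven survival gene, rose 183-fold, and NFKB1 4.97-fold.

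Dendritic cell maturation genes rose in 27 of 34 cases (27 adjusted over the list alone, camera, adjusted p = 2.84e-13), while SOCS2 and KDM2B fell. CD83, a marker of mature dendritic cells, rose 33.5-fold to 1170 ± 54.6 CPM, and SLAMF7 18.7-fold to 1040 ± 39.1 CPM. Of 23 MHC class II presentation genes 18 rose (18 adjusted over the list alone, camera, adjusted p = 1.28e-10). HLA-DRA rose 6.81-fold and HLA-DQA1 7.58-fold, with reads uncertain between HLA paralogs. Of 22 MHC class I genes 17 rose (17 adjusted over the list alone, camera, adjusted p = 1.41e-05), a call lost at adjusted p = 0.0717 with an estimated correlation. TAP1, a peptide transporter, rose 5.21-fold and B2M 2.7-fold. Of 25 interferon receptors and JAK-STAT regulators 17 rose and of 39 nucleic acid sensing genes 24 rose and 10 fell (17, 24 and 10 adjusted over the list alone), with camera adjusted p of 9.44e-07 and 0.00592. STAT1 rose 16.5-fold, the RNA sensors IFIH1 (MDA5) 83.4-fold and DDX58 (RIG-I) 41.3-fold, and TLR7 1.77-fold, while NLRP3 fell to 0.164-fold.

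Growth and lipid genes fell at 6 h. Of 35 MYC and ribosome biogenesis genes 31 fell (32 adjusted over the list alone, camera, adjusted p = 1.79e-10), including ODC1, the first enzyme of polyamine synthesis, to 0.29-fold and the nucleolar factor NOLC1 to 0.462-fold. Of 31 cholesterol and lipid synthesis genes 22 fell (23 adjusted over the list alone, camera, adjusted p = 6.93e-07), including the desaturases FADS1 to 0.213-fold and SCD to 0.364-fold. NSDHL, FDPS and STARD4 rose. Of 37 G2 and mitosis genes 23 rose (23 adjusted over the list alone, camera, adjusted p = 2.54e-05), with a median log2 fold change of 0.44, and this call was lost at adjusted p = 0.166 with an estimated correlation. The mitotic kinesin KIF2C rose 1.68-fold. The largest falls included MDFI, an inhibitor of myogenic transcription factors, from 3.73 ± 0.345 to 0.07 ± 0.0783 CPM.

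Other lists moved in part at 6 h. Of 36 p53 and cell death genes 18 rose (19 adjusted over the list alone, camera, adjusted p = 0.00592), among them CASP7 at 7.18-fold and BTG2 at 5.44-fold. Of 29 heat shock and oxidative stress genes 16 rose (16 adjusted over the list alone, camera, adjusted p = 0.00592), and this call was lost at adjusted p = 0.0717 with an estimated correlation. The thioredoxin gene TXN rose 3.8-fold. Of 30 immediate early genes 14 rose (15 adjusted over the list alone, camera, adjusted p = 0.0228), lost at adjusted p = 0.37 with an estimated correlation, with DUSP5 at 6.07-fold. Of 76 cytosolic ribosomal proteins 31 fell (29 adjusted over the list alone, 48 over all genes with GC offsets, camera, adjusted p = 0.00193), lost at adjusted p = 0.386 with an estimated correlation, with RPL4 at 0.717-fold. Plasmacytoid dendritic cell identity genes split, 12 up and 20 down of 40 (12 and 20 adjusted over the list alone, camera, adjusted p = 0.199).

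The remaining lists were not called at 6 h, with camera adjusted p of 0.634 for S phase, 0.0827 for glycolysis and hypoxia, 0.132 for the unfolded protein response, 0.548 for histones and 0.458 for the IRF family. Markers of other cell types were not called either, at 0.561 for conventional dendritic cells, 0.984 for monocytes, 0.28 for T and NK cells, 0.199 for B cells and 0.918 for stromal and epithelial cells. WARS and PPP1R15A of the unfolded protein list rose 2.16- and 4.49-fold, and PFKM of glycolysis fell to 0.265-fold.

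Of the IRF family at 6 h, IRF1, IRF2, IRF4, IRF7 and IRF9 rose, and IRF5, IRF8, IRF2BP1, IRF2BP2 and C14orf4 fell (5 and 5 adjusted over the list alone, 6 and 3 over all genes with GC offsets). IRF9, the DNA-binding subunit of the interferon-activated ISGF3 complex, rose 13.5-fold to 170 ± 12.7 CPM. IRF7, the main driver of interferon alpha genes in plasmacytoid cells, rose 2.44-fold by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0167). IRF5, named in the series' title, stood at 85.8 ± 10.6 against 116 ± 12.6 CPM, a log2 fold change of -0.44 ± 0.16 by the same edgeR test (adjusted p = 0.0249). IRF3, which carries interferon induction downstream of RIG-I, stood at 45.1 ± 8.41 against 46.6 ± 8.55 CPM and did not pass the same edgeR test (adjusted p = 0.898). The IRF5 call was lost without R848 replicate 1 (adjusted p = 0.121), without vehicle replicate 1 (0.109) and with GC offsets (0.081), and the IRF3 change turned to 0.26 (adjusted p = 0.0107) with GC offsets by the same edgeR test. The IRF7 call was lost without R848 replicate 2 (adjusted p = 0.0599), vehicle replicate 2 (0.0521) or vehicle replicate 3 (0.0544) by the same edgeR test.

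Altogether 7908 genes passed edgeR's quasi-likelihood test at 6 h, 3959 higher and 3949 lower, of which 2916 reached an absolute log2 fold change of 1. Of 28 lists 16 were called by camera, and 11 held with an estimated correlation.

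**Figure D2:**
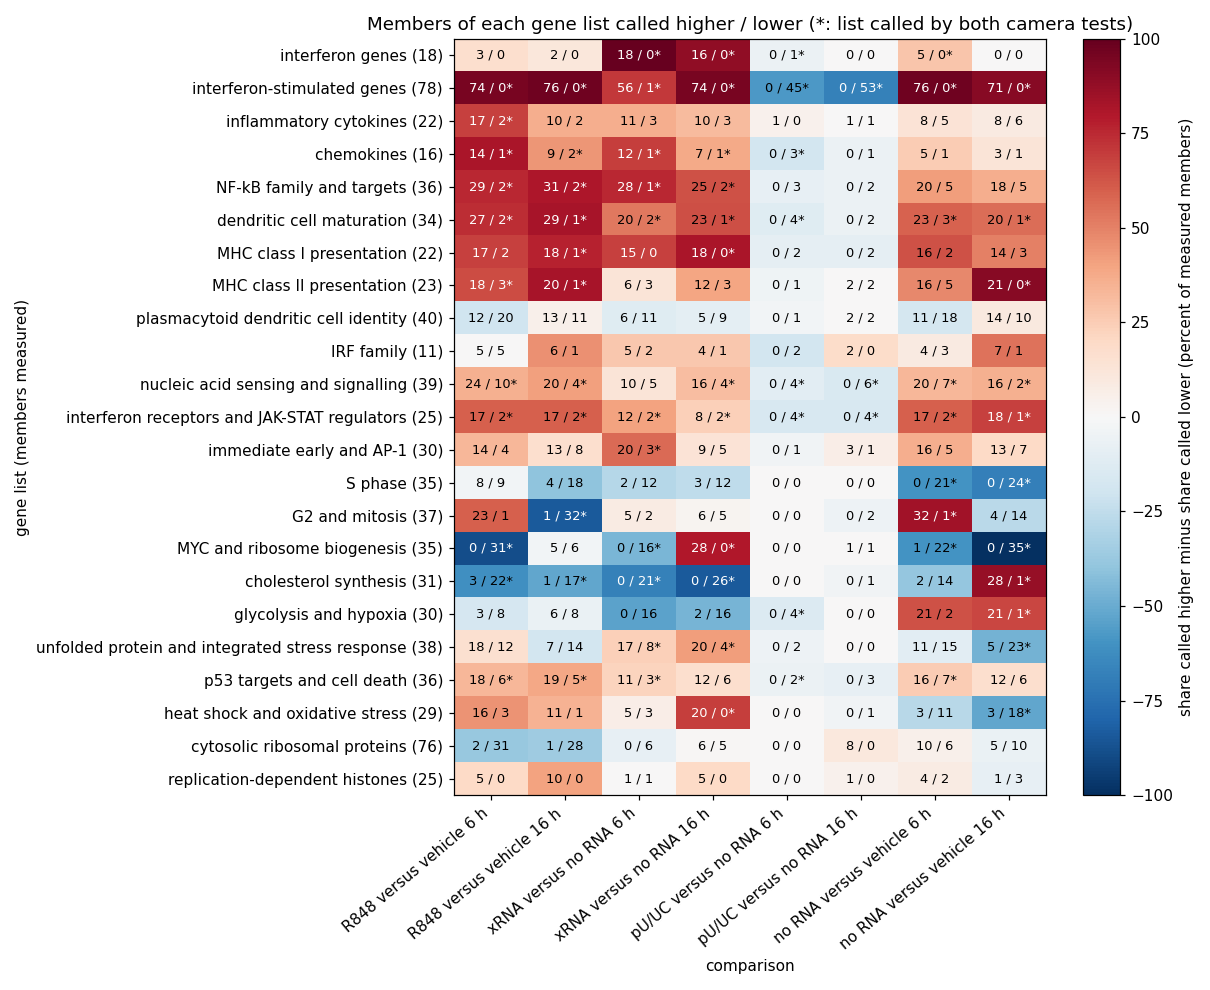
Gene lists by comparison, with each cell giving the number of measured members that rose and fell and its colour the share higher minus the share lower, for 23 lists and 8 comparisons, where * marks lists called by camera with both preset and estimated correlation. Interferon-stimulated genes rose in 74 of 78 cases with R848 at 6 h and in 76 without RNA against vehicle at 6 h, and fell in 45 cases with pU/UC against no RNA at 6 h.

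In the R848 libraries labelled 16 h, interferon-stimulated genes lay far above vehicle, with 76 of 78 higher (76 adjusted over the list alone, camera, adjusted p = 2.57e-72). The median log2 fold change was 4.17, or 4.09 with 5 genes at their bounds. IFI44L rose from 0.0698 ± 0.0606 to 488 ± 24.2 CPM, and IFIT1 from 0.0568 ± 0.0462 to 350 ± 5 CPM. MX1 rose 628-fold and OAS1 244-fold. IFNB1 was at 0.505 ± 0.229 CPM against no count, at least 22.6-fold higher. It was 1 of the 2 interferon genes of 18 that rose, beside IFNE (1 adjusted over the list alone), and the list was not called (camera, adjusted p = 0.412). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the largest adjusted p among these named genes except IFNE was 1.90e-05.

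CCL22 rose 414-fold to 494 ± 15.8 CPM at 16 h, and CCR7, the receptor that guides mature dendritic cells to lymph nodes, rose 2170-fold to 1010 ± 63.5 CPM. Maturation genes rose in 29 of 34 cases, NF-kB genes in 31 of 36, MHC class II genes in 20 of 23 and class I genes in 18 of 22 (29, 31, 20 and 18 adjusted over the list alone). Their camera adjusted p were 5.13e-20, 1.31e-17, 5.14e-16 and 5.60e-11. Chemokines rose in 9 of 16 cases (10 adjusted over the list alone, camera, adjusted p = 8.93e-05) and cytokines in 10 of 22 (10 adjusted over the list alone, camera, adjusted p = 0.000395), the latter lost at adjusted p = 0.0506 with an estimated correlation. TNFSF13B, the B cell factor BAFF, rose 110-fold to 30.9 ± 0.144 CPM, while TNF at 175 ± 6.79 against 168 ± 8.44 CPM did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.678). CXCL10, an interferon-induced chemokine, was at 2.46 ± 0.289 CPM against no count, at least 110-fold higher.

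Proliferation genes lay below vehicle at 16 h. Of 37 G2 and mitosis genes 32 fell (33 adjusted over the list alone, camera, adjusted p = 5.64e-11), with the kinesin KIF20A at 0.573-fold and the centromeric histone CENPA at 0.529-fold, while BUB3 rose. Of 35 S phase genes 18 fell (20 adjusted over the list alone, 28 over all genes with GC offsets, camera, adjusted p = 0.00257), lost at adjusted p = 0.197 with an estimated correlation, with TYMS at 0.759-fold. Of 31 cholesterol genes 17 fell (17 adjusted over the list alone, camera, adjusted p = 4.03e-05), with FADS1 at 0.29-fold. NOP2, POLR1A, POLR1C, PES1 and CIRH1A of the MYC and ribosome biogenesis list were higher and 6 lower (5 and 6 adjusted over the list alone, 7 and 16 over all genes with GC offsets, camera, adjusted p = 0.763). HMOX1, the haem-degrading stress enzyme, rose 42.4-fold to 98.7 ± 12.7 CPM and TXN 6.64-fold, in a list with 11 of 29 higher (11 adjusted over the list alone, camera, adjusted p = 0.00291), lost at adjusted p = 0.0506 with an estimated correlation. Histone genes rose in 10 of 25 cases (10 adjusted over the list alone, camera, adjusted p = 0.00311), lost at adjusted p = 0.105 with an estimated correlation, with HIST2H2BE at 5.86-fold.

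Of 11 conventional dendritic cell markers 7 fell and CADM1, BATF3, ITGAX and SIRPA rose (7 and 4 adjusted over the list alone, camera, adjusted p = 0.0125), lost at adjusted p = 0.0503 with an estimated correlation and 0.0909 with GC offsets. The largest falls included VPREB1, a surrogate light chain of B cell precursors, from 4.95 ± 0.209 to 0.128 ± 0.113 CPM, and the transcription factor ETV1 from 6.61 ± 0.649 to 0.188 ± 0.0659 CPM. IRF7 rose 6.19-fold to 121 ± 30.7 CPM and IRF2 3.41-fold. IRF5 stood at 133 ± 10.1 against 91.7 ± 11 CPM, a log2 fold change of 0.54 ± 0.16 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0094), lost without vehicle replicate 3 (0.44, adjusted p = 0.0603). IRF3, at 60.4 ± 7.3 against 47.3 ± 5.13 CPM, did not pass the same edgeR test (adjusted p = 0.327), but passed it with only the compared groups (0.0147) and with GC offsets (0.0365). Of all genes, 5876 passed the edgeR test, 2799 higher and 3077 lower, with 1828 at an absolute log2 fold change of 1 or more. Of 28 lists 19 were called, and 11 held with an estimated correlation.

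The R848 effect differed between 16 h and 6 h in 4541 genes, 2259 with a higher and 2282 with a lower fold change at 16 h. G2 and mitosis genes had a lower effect at 16 h in 34 of 37 cases (35 adjusted over the list alone, camera, adjusted p = 2.71e-22), with a median difference of -0.97. MYC and ribosome biogenesis genes had a higher effect in 30 of 35 cases (32 adjusted over the list alone, camera, adjusted p = 6.43e-15), with a median difference of 0.73. Interferon-stimulated genes had a higher effect in 33 cases and a lower in 8 of 78 (34 and 10 adjusted over the list alone, 39 and 13 over all genes with GC offsets, camera, adjusted p = 8.88e-05). Chemokines had a median difference of -4.22 (camera, adjusted p = 5.21e-07), although only CCL1 and CCL2 passed the single-gene test with a lower and CCL22 with a higher effect (2 and 1 adjusted over the list alone). The effect on 7 of 11 conventional dendritic cell markers was lower at 16 h (7 adjusted over the list alone, camera, adjusted p = 0.000772). IRF5 differed by 0.97 ± 0.23, below vehicle at 6 h and above it at 16 h, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.00186). FCAMR, an Fc receptor for IgA and IgM, stood at 6.11 ± 0.479 CPM with R848 at 6 h and 0.0683 ± 0.0433 CPM at 16 h, against 0.0221 ± 0.00315 and 0.0569 ± 0.0282 CPM in vehicle. Of genes higher at 6 h and 16 h, 2037 were shared against 793 for independent lists, and of genes lower, 1865 against 870. Of 11 lists called, 5 held with an estimated correlation.

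The comparison of pU/UC with no RNA asked how the RIG-I ligand changed nucleofected cells. At 6 h, 45 of 78 interferon-stimulated genes were lower in the libraries labelled pU/UC (60 adjusted over the list alone), with a median log2 fold change of -0.47 (camera, adjusted p = 1.89e-78). IFIT1 stood at 146 ± 15.4 against 278 ± 21.7 CPM without RNA, IFI44 at 6.97 ± 0.464 against 15.5 ± 2.23 CPM, and USP18, a negative regulator of interferon signalling, at 97.6 ± 4.14 against 140 ± 2.53 CPM. CXCL10 was at 0.056 ± 0.0499 against 0.51 ± 0.291 CPM, and CCR7 at 7.54 ± 0.404 against 16.2 ± 1.1 CPM. Among these genes, the largest adjusted p was 0.00247 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the 18 interferon genes, 11 of which had a group without counts, only IFNB1 passed the test, at 0.384 ± 0.297 against 1.28 ± 0.272 CPM (1 adjusted over the list alone, 3 lower over all genes with GC offsets, camera, adjusted p = 6.67e-05).

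DDX58, the gene of RIG-I itself, fell to 0.617-fold at 6 h, and the sensors IFIH1 and AIM2 fell to 0.628- and 0.468-fold. With IFI16, these were the 4 of 39 sensing genes that fell (8 adjusted over the list alone, 11 over all genes with GC offsets, camera, adjusted p = 0.000179). STAT1, STAT2, STAT3 and USP18 fell among 25 JAK-STAT genes (4 adjusted over the list alone, camera, adjusted p = 7.50e-05), with STAT2 at 0.744-fold. CD69, an early activation marker, fell to 0.276-fold, and CD83, CCR7 and SLAMF7 fell with it in the maturation list of 34 (6 adjusted over the list alone, 8 over all genes with GC offsets, camera, adjusted p = 0.00117). PDK1, BNIP3, EGLN3 and ANKRD37 fell among 30 glycolysis and hypoxia genes (10 adjusted over the list alone, 11 over all genes with GC offsets, camera, adjusted p = 1.92e-11). Among the few rises were PMEPA1, an inhibitor of TGF-beta signalling, at 1.77-fold, and the dendritic cell marker CD1C, the only 1 of 11 conventional dendritic cell markers to pass the test (1 adjusted over the list alone, camera, adjusted p = 0.00809). IRF3, IRF5, IRF7, TNF and IL29 did not pass the edgeR test, with folds of 1.21, 1.2, 1.01, 1.15 and 0.635.

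In all, 180 genes passed edgeR's quasi-likelihood test at 6 h, 37 higher and 143 lower (23 and 179 with DESeq2 size factors), 18 of them by an absolute log2 fold change of 1 or more, and 9 of 13 called lists held with an estimated correlation. The count was 26 in a fit of the compared groups alone, 328 with DESeq2, 608 with GC offsets, and 276, 98 and 116 without pU/UC replicate 1, 2 and 3. With only the compared groups, the calls of CD69, PMEPA1, AIM2, IFIH1, STAT2, DDX58 and IFNB1 were lost (adjusted p of 0.0788, 0.0866, 0.0932, 0.0596, 0.0777, 0.0819 and 0.607 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). By the same edgeR test, the IFNB1 call was lost without no RNA replicate 1, 2 or 3 (adjusted p of 0.0624, 0.0531 and 0.169) and pU/UC replicate 2 or 3 (0.111 and 0.0563). The DDX58 call was lost without no RNA replicate 3 (0.113) and pU/UC replicate 2 or 3 (0.135 and 0.0898), and IRF7 turned to -0.35 (adjusted p = 0.0291) with GC offsets, by the same edgeR test.

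At 16 h, 53 of 78 interferon-stimulated genes were lower in the libraries labelled pU/UC than without RNA (58 adjusted over the list alone, camera, adjusted p = 1.38e-54), with a median log2 fold change of -0.61, or -0.60 with 1 gene at its bound. IFI44 stood at 3.09 ± 0.2 against 13.8 ± 0.913 CPM, IFIT1 at 6.53 ± 1.25 against 23.2 ± 1.78 CPM and OAS3 at 10.1 ± 2.04 against 31.5 ± 4.97 CPM. IFI44L fell to 0.317-fold, STAT1 to 0.66-fold, IFIH1 to 0.58-fold, DDX58 to 0.467-fold and CCL22 to 0.623-fold. The long noncoding RNA KCNQ1OT1 stood at 0.842 ± 0.246 against 2.81 ± 0.33 CPM, and the proliferation marker MKI67 at 0.67-fold. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the largest adjusted p among these genes was 0.00106.

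IL1B rose 1.63-fold at 16 h while TNFSF13B fell among 22 cytokines (1 and 1 adjusted over the list alone, camera, adjusted p = 0.432). The conventional dendritic cell markers CD1C, CLEC10A, CD1A and CD1E rose among 11 (4 adjusted over the list alone, camera, adjusted p = 0.000492). Cytosolic ribosomal proteins rose in 8 of 76 cases (14 adjusted over the list alone, 35 over all genes with GC offsets, camera, adjusted p = 8.64e-15), lost at adjusted p = 0.089 with an estimated correlation. MHC class II genes were called higher by camera (adjusted p = 0.00649, and 0.504 with an estimated correlation), with HLA-DPA1 and HLA-DMB higher and HLA-DOB and LGMN lower (9 and 2 adjusted over the list alone, 9 and 3 over all genes with GC offsets). IRF3 and IRF5 did not pass the edgeR test, with folds of 1.31 and 1.16. In all, 561 genes passed it, 99 higher and 462 lower, 60 by an absolute log2 fold change of 1 or more, and 4 of 8 called lists held with an estimated correlation. The count was 64 with only the compared groups, 354 with no filter, 1501 with GC offsets, 236 and 327 without no RNA replicate 1 and 2, and 239, 902 and 269 without pU/UC replicate 1, 2 and 3. The share of higher genes was 17.6%, and 39.8% with GC offsets. With only the compared groups, DDX58, KCNQ1OT1, MKI67 and IL1B did not pass (adjusted p of 0.0699, 0.0557, 0.085 and 0.233 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

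The pU/UC effect differed between 16 h and 6 h in 72 genes, 9 with a higher and 63 with a lower effect at 16 h. Among the latter were the interferon-stimulated genes OAS1, OAS2, IFIT1, IFI44 and C19orf66 (10 adjusted over the list alone, 12 over all genes with GC offsets, camera, adjusted p = 0.00235), a call lost at adjusted p = 0.14 with an estimated correlation. Interferon genes were called with a higher effect (camera, adjusted p = 0.00235, and 0.0337 with an estimated correlation), the only 1 of 10 called lists to hold, although 16 of its 18 members had a group without counts at 16 h. NEDD9, a focal adhesion scaffold, had a fold change at 16 h that was higher by 0.50 ± 0.08, and KCNQ1OT1 one that was lower by a log2 difference of -2.23 ± 0.45, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.00156 and 0.0164). Both calls were lost with only the compared groups (0.121 and 0.0603 by the same edgeR test). The KCNQ1OT1 call was also lost without no RNA 16 h replicate 2 (0.0546), no RNA 6 h replicate 1 (0.072), pU/UC 16 h replicate 3 (0.0585) and pU/UC 6 h replicate 2 or 3 (0.0595 and 0.0584). The count was 11 with only the compared groups, 152 with DESeq2 and 518 with GC offsets. It was 41 without no RNA 16 h replicate 1, 30 without no RNA 6 h replicate 1, 35 and 125 without pU/UC 16 h replicate 1 and 2, and 44 without pU/UC 6 h replicate 2, and the share of higher genes was 12.5%, or 30.9% with GC offsets and 30.3% with DESeq2.

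The comparison of xRNA with no RNA measured the response to the RNA named as a control. At 6 h, all 18 measured interferon genes rose in the libraries labelled xRNA (18 adjusted over the list alone, camera, adjusted p = 2.54e-38), with a median log2 fold change of 7.86, or 7.0 with 5 genes at their bounds. IFNB1 rose 121-fold to 155 ± 7.12 CPM, and IL29 135-fold to 208 ± 61.5 CPM. IFNA21 and IFNA4 had no count without RNA and were at least 188-fold and 118-fold higher, with reads uncertain among the near-identical interferon alpha genes. Interferon-stimulated genes rose in 56 of 78 cases (58 adjusted over the list alone, camera, adjusted p = 4.74e-20), with IFIT1 at 2.35-fold and DDX58 at 2.99-fold. CXCL10 rose 37.1-fold to 18.8 ± 0.935 CPM, IL6 84.5-fold to 8.18 ± 0.174 CPM and TNF 1.68-fold. Among these genes, the largest adjusted p was 5.06e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

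Chemokines rose at 6 h of xRNA in 12 of 16 cases, NF-kB genes in 28 of 36, immediate early genes in 20 of 30 and maturation genes in 20 of 34 (12, 30, 21 and 21 adjusted over the list alone), with camera adjusted p of 3.12e-14, 5.95e-16, 4.93e-11 and 1.57e-12. Cholesterol genes fell in 21 of 31 cases and MYC and ribosome biogenesis genes in 16 of 35 (22 and 16 adjusted over the list alone), with camera adjusted p of 8.66e-11 and 1.29e-05. Of 11 conventional dendritic cell markers, CD1C, CLEC10A, CD1A, SIRPA and FLT3 fell and FCER1A and ITGAX rose (6 and 3 adjusted over the list alone, camera, adjusted p = 0.0328), lost at adjusted p = 0.0725 with an estimated correlation and 0.053 with GC offsets. BAALC, a gene of haematopoietic progenitors, was at 4.43 ± 0.692 CPM against no count, at least 142-fold higher. SLAMF8 fell to 0.082-fold and MARCH1, a ubiquitin ligase of MHC class II, to 0.128-fold. IRF3 and IRF7 did not pass, with folds of 1.02 and 1.71, though IRF7 did with GC offsets (0.54, adjusted p = 3.24e-05 by edgeR's quasi-likelihood test).

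IRF5, at 109 ± 20.6 against 80.1 ± 6.68 CPM, had an adjusted p of 0.0456 at 6 h by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. This call was lost without no RNA replicate 1, 2 or 3 (0.159, 0.0526 and 0.103), without xRNA replicate 1 (0.273), with voom (0.0701), with only the compared groups (0.0577) and with the replicate number as a block (0.06). In all, 3672 genes passed, 1850 higher and 1822 lower, with 770 at an absolute log2 fold change of 1 or more. The count was 2416 with only the compared groups and 5712 with GC offsets, and 11 of 16 called lists held with an estimated correlation. Of the genes higher in xRNA at 6 h, 1168 were also higher with R848 at 6 h, against 524 for independent lists.

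At 16 h, 16 of 18 interferon genes were still higher in the libraries labelled xRNA (18 adjusted over the list alone, camera, adjusted p = 1.94e-15), with a median of 5.48, or 2.58 with 14 genes at their bounds. Interferon-stimulated genes were higher in 74 of 78 cases (75 adjusted over the list alone, camera, adjusted p = 4.65e-44). IFNB1 was at 3.35 ± 0.417 against 0.0633 ± 0.0668 CPM, IFIT1 rose 13.4-fold to 311 ± 35.9 CPM and DDX58 6.37-fold. CXCL10 was at 3.76 ± 0.222 against 0.00968 ± 0.0168 CPM. IL28B, a type III interferon whose reads are uncertain against IL28A, was at least 51.3-fold higher, and TREML1 and TRIM29 at least 109- and 89.6-fold. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the largest adjusted p among these genes was 8.02e-06.

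MYC and ribosome biogenesis genes rose at 16 h of xRNA in 28 of 35 cases, heat shock genes in 20 of 29 and unfolded protein response genes in 20 of 38 (29, 20 and 21 adjusted over the list alone), with camera adjusted p of 6.10e-12, 1.80e-07 and 2.14e-06. Cholesterol genes fell in 26 of 31 cases (27 adjusted over the list alone, camera, adjusted p = 2.32e-13). Of 11 conventional dendritic cell markers 6 fell and SIRPA rose (6 and 1 adjusted over the list alone, camera, adjusted p = 0.000434), with CLEC10A, a lectin receptor, at 1.08 ± 0.111 against 19.6 ± 2.55 CPM. SLAMF8 was at 0.0282 ± 0.00339 against 4.79 ± 0.456 CPM, and THBD, the gene of thrombomodulin, fell to 0.117-fold. IRF3, IRF5, IRF7 and TNF did not pass, with folds of 1.12, 0.928, 1.58 and 0.923, though IRF5 (-0.19, adjusted p = 0.00946) and IRF7 (0.48, adjusted p = 0.000119) passed edgeR's quasi-likelihood test with GC offsets. In all, 4978 genes passed, 2504 higher and 2474 lower, with 987 at an absolute log2 fold change of 1 or more, and 13 of 18 called lists held with an estimated correlation.

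The libraries labelled pU/UC were also compared with those labelled xRNA, 2 RNAs delivered the same way. At 6 h, all 18 interferon genes (18 adjusted over the list alone, camera, adjusted p = 2.44e-36) and 67 of 78 interferon-stimulated genes (70 adjusted over the list alone, camera, adjusted p = 1.44e-38) were lower in pU/UC. The interferon gene median was -8.95, or -7.73 with 9 genes at their bounds. IFIT2 stood at 48.2 ± 3.77 against 3590 ± 354 CPM, HERC5, the ligase that attaches ISG15, at 32.6 ± 3.41 against 576 ± 66.1 CPM and CCL5 at 3.89 ± 1.18 against 545 ± 54.9 CPM. CXCL11 stood at 0.797 ± 0.223 against 172 ± 41.1 CPM, CCR7 at 7.54 ± 0.404 against 789 ± 152 CPM and TNFSF15 at 2.4 ± 0.152 against 140 ± 18.8 CPM. AFAP1, an actin filament-associated protein, was at 0.0284 ± 0.0309 against 72.6 ± 6.88 CPM. Among these genes, the largest adjusted p was 1.81e-12 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

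XBP1, a transcription factor of the unfolded protein response, stood at 43.7 ± 3.14 CPM in pU/UC against 474 ± 30.7 CPM in xRNA at 6 h, and WARS at 241 ± 3.81 against 1230 ± 50.5 CPM. PMAIP1, the death gene NOXA, was at 67.6 ± 6.26 against 659 ± 100 CPM and BCL2L11 at 0.276-fold. Chemokines were lower in 13 of 16 cases, NF-kB genes in 28 of 36, MHC class I genes in 19 of 22 and immediate early genes in 19 of 30 (13, 29, 21 and 19 adjusted over the list alone), with camera adjusted p of 2.72e-14, 3.50e-16, 2.29e-09 and 2.04e-08. Cholesterol genes were higher in 20 of 31 cases and MYC genes in 19 of 35 (22 and 22 adjusted over the list alone), with camera adjusted p of 1.42e-08 and 1.65e-06. SCD was 1.75-fold and ODC1 1.61-fold higher. Conventional dendritic cell markers were higher in 6 of 11 cases (6 adjusted over the list alone, camera, adjusted p = 0.00749). GZMB, a granzyme gene, was at 10.2 ± 0.797 against 41.6 ± 11.9 CPM, while 15 of 40 plasmacytoid identity genes were higher and 6 lower (16 and 6 adjusted over the list alone, camera, adjusted p = 0.115). In all, 4336 genes passed, 2277 higher and 2059 lower in pU/UC (1815 and 2349 with DESeq2 size factors), 996 by an absolute log2 fold change of 1 or more, and 14 of 17 called lists held with an estimated correlation. The count was 2376 with only the compared groups.

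At 16 h, 16 of 18 interferon genes (18 adjusted over the list alone, camera, adjusted p = 6.44e-15) and 75 of 78 interferon-stimulated genes (75 adjusted over the list alone, camera, adjusted p = 2.58e-59) were lower in pU/UC than in xRNA. OASL stood at 7.46 ± 0.807 against 178 ± 2.19 CPM, IFIT2 at 3.53 ± 0.597 against 263 ± 28.1 CPM, CCL22 at 16 ± 0.137 against 344 ± 25.1 CPM and GZMB at 8.25 ± 1.26 against 93.3 ± 5.78 CPM. DDX58 and TLR7 were lower, at 0.0732- and 0.381-fold. Cholesterol genes were higher in 28 of 31 cases (31 adjusted over the list alone, camera, adjusted p = 6.40e-15), while MYC genes were lower in 26 of 35 and heat shock genes in 17 of 29 (27 and 18 adjusted over the list alone), with camera adjusted p of 6.56e-11 and 1.20e-06. HSPA5, the ER chaperone BiP, was at 0.443-fold and TXN at 0.295-fold. Glycolysis and hypoxia genes were higher in 18 of 30 cases (20 adjusted over the list alone, camera, adjusted p = 2.16e-06), lost at adjusted p = 0.0726 with an estimated correlation, with NDRG1 at 3.76-fold. Conventional dendritic cell markers were higher in 6 of 11 cases (8 adjusted over the list alone, camera, adjusted p = 2.45e-05), with CLEC10A at 30.9 ± 4.14 against 1.08 ± 0.111 CPM. IRF5 did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (1.25-fold, adjusted p = 0.123), but did without pU/UC replicate 2 (0.0358) or xRNA replicate 1 (0.0419). In all, 5052 genes passed, 2509 higher and 2543 lower, 1179 by an absolute log2 fold change of 1 or more, and 13 of 15 called lists held with an estimated correlation. The count was 3146 with only the compared groups.

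The no RNA and vehicle libraries, the baselines of the 2 arms, differed from each other. At 6 h, 76 of 78 interferon-stimulated genes were higher without RNA than in vehicle (76 adjusted over the list alone, camera, adjusted p = 1.17e-64), with a median of 3.75, or 3.54 with 3 genes at their bounds. IFIT1 stood at 278 ± 21.7 against 0.145 ± 0.0997 CPM, IFI44L at 81.3 ± 3.42 against 0.0499 ± 0.0654 CPM and DDX58 at 94.6 ± 9.98 against 1.94 ± 0.704 CPM. IFI44 was at least 711-fold higher. IFNB1 was at 1.28 ± 0.272 against 0.0812 ± 0.0532 CPM, and with IFNA8, IL29, IL28A and IL28B it was among the 5 of 18 interferon genes that were higher (4 adjusted over the list alone, camera, adjusted p = 0.0202), a call lost with GC offsets (camera, adjusted p = 0.126). G2 and mitosis genes were higher in 32 of 37 cases (32 adjusted over the list alone, camera, adjusted p = 2.18e-09) and S phase genes lower in 21 of 35 (22 adjusted over the list alone, camera, adjusted p = 6.94e-07). Of 7 monocyte and macrophage markers 6 were higher (6 adjusted over the list alone, camera, adjusted p = 0.00102). SERPINB2, a protease inhibitor, stood at 0.114 ± 0.0645 against 5.22 ± 0.654 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the largest adjusted p among IFIT1, IFI44L, DDX58, IFI44, IFNB1 and SERPINB2 was 2.13e-06.

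IRF5 stood at 80.1 ± 6.68 without RNA against 116 ± 12.6 CPM in vehicle at 6 h by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.00875), a call lost with GC offsets (0.242) and without vehicle replicate 1 (0.0621). At 16 h it stood at 146 ± 16.1 against 91.7 ± 11 CPM (adjusted p = 0.00145 by the same edgeR test). IRF7 did not pass at 6 h (1.59-fold, adjusted p = 0.221 by the same edgeR test), and it was 3.31-fold higher at 16 h. At 6 h it passed that edgeR test with only the compared groups (log2 fold change 0.68, adjusted p = 0.00873). With GC offsets it passed at 6 h with a larger log2 fold change of 1.43 (adjusted p = 4.88e-13). In all, 6756 genes passed at 6 h, 3431 higher and 3325 lower (3238 and 4634 with GC offsets), with 10 of 18 called lists held under an estimated correlation.

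At 16 h without RNA, 71 of 78 interferon-stimulated genes lay above vehicle (71 adjusted over the list alone, camera, adjusted p = 1.14e-48), with XAF1, a proapoptotic interferon-induced gene, at 128 ± 6.98 against 0.0454 ± 0.0078 CPM. All 35 MYC and ribosome biogenesis genes were lower (35 adjusted over the list alone, camera, adjusted p = 3.64e-16), with a median of -0.70. Cholesterol genes were higher in 28 of 31 cases and MHC class II genes in 21 of 23 (28 and 21 adjusted over the list alone), with camera adjusted p of 3.39e-17 and 5.28e-12. S phase genes were lower in 24 of 35 cases, unfolded protein genes in 23 of 38 and heat shock genes in 18 of 29 (24, 24 and 19 adjusted over the list alone), with camera adjusted p of 3.01e-08, 0.000596 and 6.05e-05. LYZ, CSF1R, FCGR1A, MS4A7 and CD68 were higher among 7 monocyte markers (5 adjusted over the list alone, camera, adjusted p = 0.00234). FCRL4, an Fc receptor-like gene of B cells, had no count without RNA and was at least 67.2-fold lower. In all, 6683 genes passed edgeR's quasi-likelihood test, 3457 higher and 3226 lower (3768 and 4768 with GC offsets), and 12 of 16 called lists held with an estimated correlation.

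The R848 effect over vehicle was contrasted with the pU/UC effect over no RNA. These baselines differ, and a difference of effects carries that difference. IFIT1 at 6 h lay at 0.041 to 0.24 CPM in vehicle and 258 to 301 CPM without RNA. It lay at 256 to 282 CPM with R848 and 133 to 163 CPM with pU/UC. At 6 h, 74 of 78 interferon-stimulated genes had a higher fold change with R848 (74 adjusted over the list alone, camera, adjusted p = 2.37e-54). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, IFIT1 differed by 11.72 ± 0.26, IFNB1 by 8.26 ± 0.62 and DDX58 by 6.07 ± 0.24 on the log2 scale, with adjusted p of at most 1.41e-10. MHC class II genes were higher in 18 of 23 cases and maturation genes in 24 of 34 (18 and 25 adjusted over the list alone), with camera adjusted p of 1.37e-11 and 4.91e-14, and MYC genes lower in 31 of 35 (31 adjusted over the list alone, camera, adjusted p = 3.86e-10). MDFI differed by -6.53 ± 0.75. IRF5 differed by -0.70 ± 0.23 (adjusted p = 0.0138 by the same edgeR test), lost without pU/UC replicate 2 (-0.56, 0.0516) and vehicle replicate 1 (-0.57, 0.0526). Of 6598 genes that passed, 3136 had a higher and 3462 a lower effect (3440 and 3106 with DESeq2 size factors), and 12 of 16 called lists held with an estimated correlation.

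At 16 h, 75 of 78 interferon-stimulated genes had a higher fold change with R848 than with pU/UC (75 adjusted over the list alone, camera, adjusted p = 4.77e-83). The baselines differed here too, with IFIT1 at 0.02 to 0.109 CPM in vehicle and 21.3 to 24.8 CPM without RNA. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, IFIT1 differed by 14.46 ± 0.29 and IRF7 by 2.25 ± 0.63 on the log2 scale (adjusted p = 1.21e-22 and 0.00682), and STYK1, a pseudokinase, by -6.17 ± 0.51. IRF5 differed by 0.32 ± 0.23 and did not pass (adjusted p = 0.312 by the same edgeR test), though it did with GC offsets (0.49, 1.45e-05). Cytosolic ribosomal proteins had a lower effect in 38 of 76 cases (41 adjusted over the list alone, 60 over all genes with GC offsets, camera, adjusted p = 8.50e-08), lost at adjusted p = 0.157 with an estimated correlation. Of 11 conventional dendritic cell markers 7 had a lower effect (7 adjusted over the list alone, camera, adjusted p = 0.0024). Of 4725 genes that passed, 2339 had a higher and 2386 a lower effect, and 11 of 17 called lists held with an estimated correlation.

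Against the xRNA effect, a contrast added after seeing the data, camera called interferon genes with a lower R848 effect at 6 h and 16 h (adjusted p = 1.51e-18 and 3.64e-11), where 16 of the 18 had a group without counts in R848 versus vehicle at either time. Interferon-stimulated genes had a higher effect with R848 in 71 of 78 cases at 6 h and 69 at 16 h, and MHC class II genes in 18 and 20 of 23 (71 and 70, and 18 and 21, adjusted over the list alone). These effects have the unlike baselines given above, so a higher effect need not be a higher level. At 6 h IFIT1 lay at 256 to 282 CPM with R848 and 634 to 685 CPM with xRNA. IFI44L lay at 176 to 195 CPM with R848 and 107 to 131 CPM with xRNA. MYC genes had a lower effect in 28 and 19 of 35 cases (28 and 23 adjusted over the list alone, and 31 at 16 h over all genes with GC offsets). At 6 h, 5527 genes passed edgeR's quasi-likelihood test, 2746 higher and 2781 lower, and at 16 h 3896, 2037 higher and 1859 lower. With GC offsets the 16 h count was 6352, 2765 higher and 3587 lower. Of 15 and 16 called lists, 8 and 12 held with an estimated correlation.

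**Figure D3:**
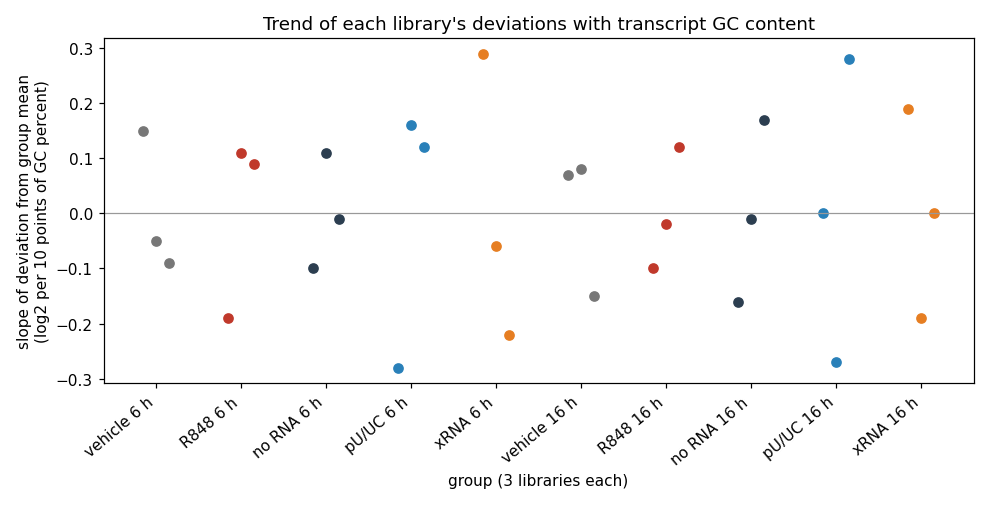
Slope of each library's deviation from its group mean on transcript GC content, in log2 units per 10 points of GC, for the 30 libraries by group. The slopes ran from -0.28 in a pU/UC 6 h library to 0.29 in an xRNA 6 h library.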

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

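For the weighing of labels in this part, the tests of a label exchange and of an active xRNA preparation were chosen only after the result was seen, as were the R848 minus xRNA contrasts.

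The R848 effect differed between the times in 4541 genes. IRF5 had a fold change higher at 16 h by 0.97 on the log2 scale and FCAMR one lower by -7.67. The pU/UC effect differed between the times in 72 genes, with NEDD9 at 0.50 and KCNQ1OT1 at -2.23. Between R848 and pU/UC, the effects differed in 6598 genes at 6 h, with IFIT1 at 11.72, IFNB1 at 8.26, DDX58 at 6.07, IRF5 at -0.70 and MDFI at -6.53. At 16 h they differed in 4725 genes, with IFIT1 at 14.46, IRF7 at 2.25 and STYK1 at -6.17. The R848 and xRNA effects differed in 5527 genes at 6 h and 3896 at 16 h. Each of these was raised by a tested difference between the effects in 2 groups. The R848 effects are over vehicle and the pU/UC and xRNA effects over no RNA, baselines that themselves differ.

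Each interaction was recomputed over 25 splits of its samples, the real one included. For the R848 effect at 16 h minus 6 h, 1 split called as many genes, the real one (4541, highest other 2991). The same 1 split stood alone for R848 minus pU/UC at 6 h (6598, highest other 1974) and 16 h (4725, highest other 2485), and for R848 minus xRNA at 6 h (5527, highest other 3442) and 16 h (3896, highest other 2955). The smallest share possible here is 1 of 25, with no adjustment over the contrasts. These splits also mixed libraries of different times or treatments, so they do not show what an absent interaction would give. A chance arrangement of the samples was therefore not excluded for these 5. For the pU/UC effect at 16 h minus 6 h, 3 of 25 splits called at least 72 genes and the highest other called 4630. Its splits mixed libraries of 6 h and 16 h and of both treatments, so that count points to a structure of the samples, and a chance arrangement was not excluded.

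Each comparison of 2 groups had 10 splits, too few to tell, and in each the real split was the 1 with the most calls. The highest other count was 1 for R848 versus vehicle at 6 h (real 7908) and 1 for no RNA versus vehicle at 6 h (real 6756). It was 0 for R848 versus vehicle at 16 h (5876), pU/UC versus no RNA at 6 h (180) and 16 h (561), xRNA versus no RNA at 6 h (3672) and 16 h (4978), pU/UC versus xRNA at 16 h (5052) and no RNA versus vehicle at 16 h (6683), all by edgeR's quasi-likelihood test. For pU/UC versus xRNA at 6 h (4336), a split that set pU/UC replicate 1 beside xRNA replicates 2 and 3 called 2939 genes. With GC offsets that split called 0 genes and the real one 6389.

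Interferon genes were high in the libraries labelled xRNA and not in those labelled pU/UC, opposite to the design text. An exchange of pU/UC and xRNA labels in only part of the libraries or at 1 time was excluded if only 1 of these RNAs raises IFNB1. For this, 0 libraries labelled pU/UC had IFNB1 above every no RNA library of their time. The no RNA labels were taken as right, and an exchange that involves them was not tested. A GC-linked bias between libraries was excluded too, since all 18 interferon genes were still higher in xRNA than in no RNA at 6 h with GC offsets. An exchange of the pU/UC and xRNA labels in all 12 libraries (6 of 6 libraries labelled xRNA had IFNB1 above every pU/UC and no RNA library of their time) and an xRNA preparation that activated the cells (18 interferon genes higher at 6 h) cannot be told apart, because either gives the same counts.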

How the results depend on the processing

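The GC offsets and the R848 minus xRNA contrasts in this part were chosen only after the result was seen. With DESeq2 size factors, a stricter filter and limma voom, all 16 counts of calls stayed within 1.5 times. With DESeq2, pU/UC versus no RNA at 6 h moved from 180 to 328 and the pU/UC effect at 16 h minus 6 h from 72 to 152. In simulations of independent genes without a GC trend, DESeq2 also called more unchanged genes than edgeR (22 among 197 calls against 3 among 173). Those counts were drawn with edgeR's own dispersion estimates for the genes its filter kept. They therefore do not show whether the added DESeq2 calls in the real counts are false. Without a filter, pU/UC versus no RNA at 16 h moved from 561 to 354. With only the compared groups, fewer samples estimate the spread and the low-count filter is also set anew. The counts were then 26 and 64 for pU/UC versus no RNA at 6 h and 16 h, 2416 for xRNA versus no RNA at 6 h, 2376 and 3146 for pU/UC versus xRNA at 6 h and 16 h, and 11 for the pU/UC effect between times. With GC offsets they were 608 and 1501 for pU/UC versus no RNA, 5712 for xRNA versus no RNA at 6 h, 518 for the pU/UC effect between times and 6352 for R848 minus xRNA at 16 h. The share of higher genes then went from 17.6% to 39.8% for pU/UC versus no RNA at 16 h and from 12.5% to 30.9% for its effect between times. GC offsets reversed IRF3 in R848 versus vehicle at 6 h to 0.26 and IRF7 in pU/UC versus no RNA at 6 h to -0.35. Leaving out 1 library at a time gave 98 to 276 genes for pU/UC versus no RNA at 6 h, 236 to 902 at 16 h and 30 to 125 for its effect between times. GC offsets lowered the common coefficient of variation between libraries of a group from 13.6% to 7.05%. They were fitted on deviations from the mean of all 30 libraries, so group differences along GC are removed too. How much each of these adds to the GC moves was not tested. The cause of the DESeq2, filter, compared-groups and leave-one-out moves was not tested either.

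Named genes kept their call, and their direction where called, in 304 of 304 cases with DESeq2, 303 with voom, 293 with GC offsets, 277 with only the compared groups (22 calls lost, 3 gained, and CXCL10 filtered out in 2 comparisons), and 1874 cases of leaving out a library (26 lost, 2 gained). Of 448 list tests, 363 kept their call with an estimated correlation, 347 with fry, 425 with GC offsets, 443 with DESeq2 size factors and 444 with a prior count of 0.5. Deviations from the group mean, taken without GC offsets, did not pair the libraries by replicate number. In 0 of 10 comparisons did every library correlate best with its own number, and 7 of 30 pairs exceeded 0.1 (range -0.89 to 0.88). With the replicate number as a block, R848 versus vehicle at 6 h had 7759 genes, pU/UC versus no RNA 163 and 481, and its effect between times 66, and 1 named call changed. The sample numbers in the column names, from S1 to S15, were not tested as a batch. In the order of the columns they form 2 sets over which the groups are spread unevenly. All vehicle 16 h libraries lie in 1 set and all no RNA 6 h and pU/UC 16 h libraries in the other. Depth limits genes near 3 counts, 0.0567 to 0.116 CPM in a library.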

Other observations

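In this part, the comparison of no RNA between times, the overlap of pU/UC with R848 and the tests of a mixture and of replicate batches were chosen only after the result was seen.

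Libraries of the no RNA groups differed between 6 h and 16 h in far more genes than vehicle libraries, with 5896 against 882 genes by edgeR's quasi-likelihood test. All no RNA 6 h libraries lie in a single set of the sample numbers described above and the no RNA 16 h libraries in both. Vehicle libraries lie mostly in the other set. Time without RNA is thus partly confounded with whatever these sets mark, and these counts were not recomputed under the alternatives. IFIT1 fell from 278 ± 21.7 to 23.2 ± 1.78 CPM without RNA, while HMGCS1, an enzyme of cholesterol synthesis, rose from 312 ± 18.4 to 1560 ± 146 CPM and stayed at 359 ± 21 and 328 ± 25.1 CPM in vehicle. LYZ, the lysozyme gene, stood at 427 ± 25 and 938 ± 53.8 CPM without RNA, and at 130 ± 16.8 and 220 ± 28 CPM in vehicle.

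Genes lower with pU/UC than without RNA were largely those that R848 raised. At 6 h, 131 of 143 (91.6%) were higher with R848 than vehicle, against 41 for independent lists, and at 16 h 276 of 462 (59.7%) against 93. The 6 h and 16 h lower genes of pU/UC shared 79 against 5.

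Interferon-stimulated genes were higher in the no RNA than in the vehicle libraries. A mixture in which transcripts of the R848 or xRNA libraries themselves supply these levels was excluded as the whole source at both times. Genes near 0 in vehicle, above 5 CPM in those libraries and outside the interferon-stimulated list reached medians of 0.00767 (R848, 19 genes) and 0.0189 (xRNA, 47 genes) of the level that such a mixture needs at 6 h, and 0.0575 (13 genes) and 0.079 (16 genes) at 16 h, with upper quartiles of at most 0.166. CCL5 at 1.05 for R848 at 6 h, TMEM140 at 0.807 and CD69 at 0.571 for xRNA at 6 h, LAMP3 at 0.514 for R848 and 2.58 for xRNA at 16 h, and C3AR1 at 1.02 for xRNA at 16 h went against this. A GC-linked bias was excluded, since 78 interferon-stimulated genes were higher at 6 h with GC offsets. The nucleofection itself stays open, since no comparison here separates it from other differences in handling between the 2 arms. An effect of a few stimulated cells, or of their medium, on the other cells stays open too. The mixture test cannot exclude it, because it counts only transcripts carried over.

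Libraries of 1 group differed along the GC content of their genes. A bias of preparation or sequencing that acts on all genes alike had the values it needs, with slopes in genes called in no contrast at 1.37 times those in called genes. Any other cause of a GC trend across all genes would give such slopes too, so they do not single out preparation or sequencing. The replicate number did not mark this trend, with 0 of 10 comparisons in which all 3 same-numbered pairs correlated by over 0.1, although 7 of 30 pairs did. The correlated deviations kept the GC trend, which can hide other effects. A shared culture or batch apart from that trend was therefore not excluded. Depth of the library cannot be told apart from the rest, with r = 0.46 over 30 libraries (permutation p = 0.0366, Benjamini-Hochberg p = 0.0527, 100000 permutations) and 0.31 without the 2 libraries farthest from the median depth. No biological explanation was tested.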
